A study of Mus musculus with 2 samples.

How the data were processed

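Colonic stromal cells of mice with floxed Il10ra alleles were compared with those of mice that also carried a Cre recombinase driven by Pdgfra. Each genotype gave 1 library, and the design text counts 2 mice of 6 months per genotype. Per the labels, libraries were made with a 10x Genomics 5' kit, which reads the start of transcripts. The cells had been sorted as living cells with Podoplanin and without CD45, CD31 or EpCAM.

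The deposited matrices hold raw UMI counts per gene and barcode, as whole numbers, for the barcodes kept by the authors' processing. The submitters' processing notes name Cell Ranger 8.0.1 and the mouse build GRCm39. Both libraries had the same 33696 features; 26 rows repeated a symbol, and the first row was used under it, a choice made after the data were seen. The annotation at hand was of another build, so gene locations were not used here. Per-sample columns left unused numbered 0.

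Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept. Doublets were called in each library with Scrublet in scanpy 1.11.5 at an expected rate of 8% and removed. In the control library 330 of 11380 barcodes failed the filter and 479 were called doublets; in the Cre library 214 of 8627 failed and 97 were called doublets. This left 10571 and 8316 cells. Scrublet set a score cutoff of 0.295 in the control and 0.42 in the Cre library. The numbers of calls therefore do not compare doublets between the libraries.

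Cells of both libraries were clustered together without integration, on 2000 variable genes, 30 components and 15 neighbours, with leidenalg 0.10.2 at resolution 1, which gave 24 clusters. Genes of the interferon, MHC, nucleic acid sensing, sex-linked, stress, cell cycle and free RNA lists and mitochondrial, ribosomal protein and antigen receptor genes were kept out of the variable genes.

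Marker genes were fixed before the data were examined, but the rule that turned them into names was not. It used the last of 4 rankings of cluster genes, settled after the clusters had been seen. The 3 that were set aside took folds against all other cells of both libraries with no detection minimum, folds within the library holding most of the cluster with no minimum, and the latter for genes in at least 25% of the cluster's cells. The ranking used took folds within the library holding most of the cluster, with 10 CPM added, for genes in at least 10% of its cells. The naming thresholds were also set after the data were seen. A cluster took the name of a type other than fibroblast with at least 3 markers among its top 30 genes. Other clusters were fibroblast-like if the mean log2 fold of the fibroblast markers was no more than 1 unit below 0, which 15 clusters were. Clusters with a median UMI count under 1/3 of that of their library stayed unnamed unless named by at least 3 markers with 1 among their top 10 genes. The fibroblast class of a cluster was subepithelial, lamina propria or adventitial, whichever's markers had the highest mean log2 fold against other fibroblast-like clusters. Markers of reticular fibroblasts, Cxcl13 among them, were fixed too but not scored, so no cluster could take that name. The class needed at least 3 markers enriched 1.5-fold and no other class with more markers among the top 10. Remaining fibroblast-like clusters kept a number and were compared with at least 200 cells per library.

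Raw counts were summed over cells per library and class and divided by the total to give CPM. Log2 ratios of Cre over control were taken with 1 CPM added, and genes with a mean of at least 10 CPM were measured. With 1 library per genotype no test between genotypes was possible, and no p-value was computed. Sums carry exact Poisson intervals, ratios of sums exact binomial intervals and shares Clopper-Pearson intervals, all at 95%; they cover counting error only. The median of each of 24 gene lists fixed in advance was placed among 10000 random lists of the same size, matched on mean CPM in 20 bins, as a description of these libraries. For interferon UMIs per cell each cell was thinned to 2000 UMIs, and shallower cells were left out.

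Named genes followed a rule fixed in advance: the 12 highest and 12 lowest log2 ratios among genes with at least 20 CPM in a library and 50 UMIs over both, the receptor and sex-linked genes, the 2 highest, 2 lowest and 2 most abundant members of each list, and 3 genes per direction in each class. The ranked genes left out Gm-number, Rik and ENSMUSG names, mitochondrial, ribosomal protein, antigen receptor, sex-linked and haemoglobin genes and the free RNA list. Hbb-bs, left out in this way, had a log2 ratio of 5.91 in fibroblast-like cells, above that of H2-Q6 at 5.53. Isg15, Ifit1, Cxcl10, Cxcl13, H2-K1 and Col1a1 were named outside this rule, after values had been seen. A result for 1 gene is not reported here.

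The steps were tested on simulated counts of the 9041 measured genes for Cre over control in fibroblast-like cells. Of 67 genes set 1.5-fold apart, 100% had the right direction and 94.0% had an interval that held the true ratio. The latter share was 95.5% for 67 genes set 2-fold apart and 95.45% for 66 genes set 4-fold apart. Of 8841 unchanged genes 0 came out 2-fold apart, and 4% of 200 unchanged lists fell outside the central 95% of random lists. The simulated libraries shared 1 profile and differed by the set folds and counting error only. These shares therefore check the computation and say nothing on differences between mice, batches or mixes of cells.

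Alternatives fixed in advance covered the cell filter, doublets, resolution, variable genes, scaling by TMM in edgeR 4.0.16 or by the median of ratios, the mean of each cell's CPM, the pseudocount, the CPM minimum, thinning, weighting of classes, the UMI minimum and separate clustering. Weighting each class alike took the mean CPM of the 3 named classes and left out the other fibroblast-like clusters. The 3 other rankings were added after the data were seen. Computation used Python 3.11.15 and R 4.3.3.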

Results

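The study asked how the IL-10 receptor alpha chain in fibroblasts affects the large intestine, and its title names type I interferon signalling. Colonic stromal cells were profiled from mice with floxed Il10ra, called control here, and from mice that also carried Pdgfra-Cre. The control library held 11380 barcodes and 76570611 UMIs, with a median of 6505 UMIs per barcode. The Cre library held 8627 barcodes and 66845139 UMIs, with a median of 7332. There was 1 library per genotype, so differences below are between 2 libraries and have no replicate check.

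The targeted gene was near the detection limit in both libraries. In fibroblast-like cells Il10ra (ENSMUSG00000032089) had 1 UMI in 65138125 in the control library, or 0.0154 CPM with a 95% interval of 0.000389 to 0.0855. It had 5 UMIs in 62093951 in the Cre library, or 0.0805 CPM with an interval of 0.0261 to 0.188. With 1 UMI in the control library a loss could not show, so these counts do not check the deletion. In addition, a 5' kit reads the start of the transcript and the labels do not name the floxed exon. Il10rb, the second chain of the receptor, was at 43.4 CPM in the control and 52.9 CPM in the Cre library, and Pdgfra at 363 and 354 CPM. Xist, expressed from the inactive X chromosome, was at 353 and 394 CPM. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d had 0 UMIs in both libraries, which allows up to 0.0566 CPM in the control and 0.0594 CPM in the Cre library, and Uty had 1 and 2.

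Fibroblast-like cells made up 89.7% of 10571 control cells (95% interval 89.05 to 90.2) and 93.4% of 8316 Cre cells (92.9 to 93.9). Smooth muscle-like cells made up 6.78% (6.31 to 7.28) and 2.20% (1.90 to 2.54), and glia-like cells 0.747% and 1.47%. Cells resembling mesothelium made up 0.577% and 0.541%, interstitial cells of Cajal 0.359% and 0.722%, and lymphatic endothelium 0.397% and 0.529%. Ptprc, which encodes the leukocyte protein CD45, had a UMI in 0.0568% of control and 0.108% of Cre cells. The sort for Podoplanin without CD45, CD31 and EpCAM, the gene minimum and the depth of each library can all set these shares.

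Among fibroblast-like cells, adventitial or trophocyte fibroblasts, marked by genes such as Pi16, Cd81 and Grem1, made up 30.55% (29.6 to 31.5) of the control and 40.6% (39.5 to 41.7) of the Cre cells. Subepithelial PDGFRA-high fibroblasts, marked by Sox6 and Bmp3, made up 12.2% (11.6 to 12.9) and 5.90% (5.38 to 6.44). Lamina propria fibroblasts, marked by Edil3 and Adamdec1, made up 49.5% and 32.4%. Clusters that met no class made up 7.76% and 21.1%. Clusters 0 and 7 held most lamina propria cells of the control and cluster 1 most of those of the Cre library. Clusters 2 and 4 held most adventitial cells of the control and clusters 3 and 6 most of those of the Cre library, while cluster 5, which also had the contractile genes Tagln and Acta2 among its leading genes, held most subepithelial cells of both. Chemokine genes Cxcl13 and Cxcl9 were among the leading genes of cluster 1, and Ifi207, Ifit1, C3 and Cfb among those of cluster 3. A cluster mostly of 1 library may be that library and not a type. Class markers such as C3, Nrg1 and Bmp7 differed between libraries over all fibroblast-like cells, and such ratios can also follow class shares. For these reasons no class is called more or less frequent. The log2 ratio of the lamina propria share was -0.61 and turned sign under 6 of 10 alternatives, that of the adventitial share was 0.41 but 0.20 with each library clustered on its own and 0.74 at resolution 2, and that of the subepithelial share was -1.05 but -1.69 with at least 200 genes and at most 20% mitochondrial UMIs per cell.

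Interferon response genes were higher in the Cre library. Of 53 measured members of the type I interferon response list, 41 were at least 1.5-fold higher in fibroblast-like cells and 0 as much lower, with a median log2 ratio of 0.91, above all 10000 random lists. Isg15, a ubiquitin-like antiviral protein, was at 62.0 CPM in the control and 225 CPM in the Cre library, a ratio of 3.63 (3.51 to 3.76). Ifit1, an antiviral RNA-binding protein, was at 11.4 and 58.9 CPM. Gm4951 was 8.78-fold higher (7.98 to 9.68) and Oas1a, a sensor of double-stranded RNA, 7.21-fold higher (6.16 to 8.49). The most abundant members, Ifitm3 and Ifi27l2a, were 1.75-fold and 2.10-fold higher, while Shisa5 was at 149 and 149.5 CPM. Ifnar1 and Ifnar2, the chains of the type I interferon receptor, were at 31.3 and 30.15 CPM and at 153.5 and 196 CPM, and the list of interferon ligands and receptors had a median of 0.056.

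Genes of the interferon gamma response and of antigen presentation were further apart. Of 28 measured members of the interferon gamma and guanylate-binding protein list, 24 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 1.78. Cxcl9, a T cell chemokine, was at 6.95 and 76.9 CPM, Cxcl10 at 115.5 and 471 CPM and Iigp1, an immunity-related GTPase, at 49.9 and 443 CPM. Of 17 measured members of the MHC class I list 15 were at least 1.5-fold higher, with a median of 1.76. H2-K1 was at 439 and 1983 CPM, H2-D1 at 785 and 2813 CPM and B2m, the light chain of class I molecules, at 700.3 and 2473 CPM. H2-Q6 (ENSMUSG00000073409) was 59.5-fold higher (52.1 to 68.3) and H2-Q7 (ENSMUSG00000060550) 34.2-fold higher (31.1 to 37.6). The log2 ratio of H2-Q7 was 4.91, against 5.645 with each class weighted alike and 3.86 with 10 CPM added. H2-Q6, H2-Q7 and H2-Q5, at 18.6-fold, are close paralogs, so the split of reads between them is uncertain. In the nucleic acid sensing list, which shares members such as Irf7, Zbp1 and Ifih1 with the type I list, 5 of 11 members were at least 1.5-fold higher and the median was 0.58, or 0.37 with 10 CPM added. Of the MHC class II list only Cd74 and H2-Ab1 were measured, at 4.18 and 18.1 CPM and at 11.5 and 24.3 CPM.

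**Figure D1:**
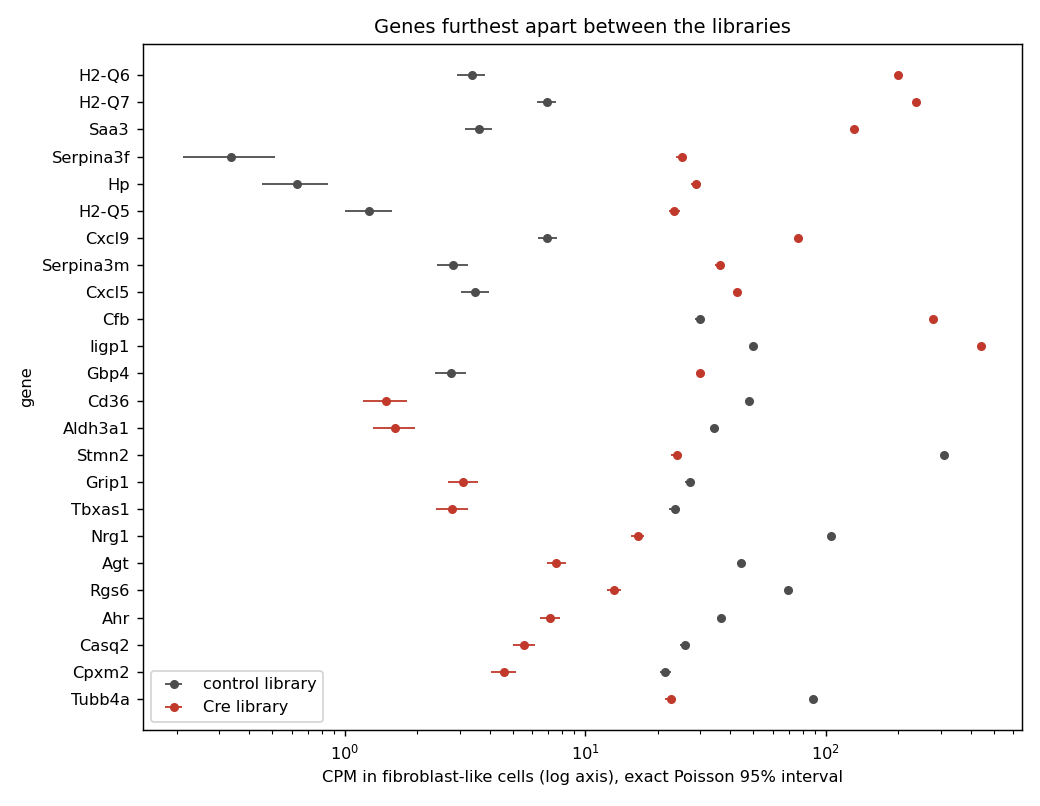
CPM in fibroblast-like cells of the 12 highest and 12 lowest genes by log2 ratio under the naming rule, which leaves out Hbb-bs. The axis is logarithmic, and exact Poisson 95% intervals cover counting error only. Grey points are the control library and red points the Cre library, 1 library each. H2-Q6 lies at 3.36 CPM in the control and 200.1 CPM in the Cre library, and Cd36 at 47.8 and 1.48 CPM.

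Most complement genes and some acute phase and chemokine genes were also higher in the Cre library. Of 12 measured complement members, which include Serping1, C1ra and C1s1 of the interferon gamma list, 8 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 1.01, or 0.61 with no CPM minimum. C3, the central complement component, was at 692 and 2976 CPM, and Cfb, a factor of the alternative pathway, was 9.34-fold higher (8.91 to 9.79). Saa3, an acute phase protein, was 36.2-fold higher (31.8 to 41.4), Hp, which encodes haptoglobin, 45.7-fold (up to 63.9), and the serine protease inhibitor gene Serpina3f 74.3-fold (48.9 to 119). Of 21 cytokine and chemokine members 10 were at least 1.5-fold higher and 1, Il34, as much lower, with a median of 0.53, or 0.84 with a minimum of 50 CPM. Cxcl5, a neutrophil chemokine, was 12.2-fold higher (up to 14.0), and Cxcl13, a B cell chemokine, was at 97.4 and 515 CPM. In the NF-kappaB and acute phase list 8 of 19 members were higher and 2 lower, with a median of 0.42, or 0.23 with each class weighted alike; the lower ones were Ptgs2 and Ptges, enzymes of prostaglandin E2 synthesis. In subepithelial fibroblasts 3 of 17 members of that list were higher and 5 lower, with a median of 0.049.

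Transcripts of other cell types differed between the same libraries. In fibroblast-like cells the haemoglobin gene Hbb-bs was at 0.430 CPM in the control and 84.8 CPM in the Cre library, and over all kept cells 0.265% and 2.26% of cells had a UMI of it. The neutrophil gene S100a9 had 0 UMIs in the control and 403 in the Cre library, from 9 cells; 0 of 10571 control cells allows a share of up to 0.0349% with a UMI, which does not limit cells that express the gene. S100a8, also of neutrophils, had 29 UMIs in 18 control cells and 373 UMIs in 9 Cre cells, or 0.170% and 0.108% of kept cells, so no direction is given for neutrophil cells. Cd74, of antigen-presenting cells, had a UMI in 1.73% of control and 7.35% of Cre cells. Jchain, of plasma cells, was at 18.7 CPM in the control and 7.15 CPM in the Cre library in fibroblast-like cells, but over all kept cells 2.53% of control and 3.49% of Cre cells had a UMI of it, so no direction is given. The immunoglobulin genes Igha and Igkc likewise had a lower CPM and a higher share of cells in the Cre library, while Ighm was higher on both measures, at 1.26 and 2.485 CPM and in 0.672% and 1.43% of kept cells. The endothelial gene Plvap was at 21.1 and 22.2 CPM. These 4 members of the free RNA list that were measured, Hbb-bs, Cd74, Jchain and Plvap, had a median log2 ratio of 0.98. They ran from 5.91 for Hbb-bs to -1.27 for Jchain, so the median gives no common direction. Cd74 is also a member of the MHC class II list.

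Some matrix genes were lower in the Cre library. Of 30 measured members of the fibrillar collagen and matrix list 9 were at least 1.5-fold lower, 1, Lox, was as much higher and 20 lay in between, and the median log2 ratio was -0.44, below all random lists. By class the median was -0.44 in lamina propria fibroblasts, where 12 of 30 were at least 1.5-fold lower and 1 higher, -0.20 in adventitial fibroblasts, with 4 of 29 lower and 1 higher, and -0.17 in subepithelial fibroblasts, where 4 of 29 were lower and 4 higher. Col3a1 was at 2895 and 1684 CPM, Postn, a matricellular protein, at 1769 and 633 CPM, and Col1a1 had a log2 ratio of -0.64. Dcn, the proteoglycan decorin, had a log2 ratio of 0.32. The myofibroblast and TGF-beta list had a median of -0.22, or -0.076 with each class weighted alike, and the hypoxia and glycolysis list one of -0.26. In the inflammation-associated fibroblast list 5 of 17 members were at least 1.5-fold higher and 4 lower. Mmp3, a matrix protease, was 4.45-fold higher and Plau 2.39-fold lower. The median was 0.43, or 0.21 with each class weighted alike, and 0.17 in lamina propria, 0.25 in adventitial and 0.34 in subepithelial fibroblasts.

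Signals to the epithelium went in both directions. Nrg1, an ErbB ligand, was at 104.7 and 16.5 CPM and Wnt4 at 171 and 66.1 CPM. Rspo3, which strengthens Wnt signalling, was at 19.5 and 61.0 CPM, and Grem1, a BMP antagonist, at 190 and 407 CPM. The list of Wnt agonists and trophic factors had 6 of 16 members at least 1.5-fold higher and 5 as much lower, and a median of -0.031 that was 0.40 with each class weighted alike and -0.30 with a minimum of 50 CPM, so no direction is given. Bmp7 and Bmp2 had log2 ratios of -1.49 and -1.42. The list of BMP and Wnt antagonist signals had a median of -0.40, which was -0.020 with each class weighted alike. Its median was -0.083 within subepithelial, -0.065 within lamina propria and -0.053 within adventitial fibroblasts. Nrg1, Wnt4, Bmp7 and Bmp2 were markers of the subepithelial class, and Rspo3 and Grem1 of the adventitial class. Ratios of such markers over all fibroblast-like cells can follow the shares of the classes. Cd36, a fatty acid transporter, was 32.3-fold lower (26.2 to 40.2), Aldh3a1, an aldehyde dehydrogenase, 21.3-fold (up to 26.3), and Stmn2, a tubulin-binding protein, 12.9-fold (12.2 to 13.6). The log2 ratios of Cd36 and Aldh3a1 were -4.30 and -3.76, against -3.51 and -2.97 with each class weighted alike and -2.33 and -1.93 with 10 CPM added. Of the 12 lowest genes, Cd36, Tbxas1, Agt and Grip1 were among the leading genes of cluster 7, which held 1187 control and 21 Cre cells. Stmn2 was among those of cluster 0, with 3112 and 148 cells, and Nrg1 among those of cluster 13, with 216 and 18. Ahr, the aryl hydrocarbon receptor, had a log2 ratio of -2.21, which was -1.19 with each class weighted alike, and that of Nrg1 was -2.60 against -1.65. Those of Grip1 and Casq2 were -2.78 and -2.05 against -1.76 and -0.98, and that of Cpxm2, 4.71-fold lower, was -1.001 with each class weighted alike.

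The IL-10 receptor and signalling list had a median log2 ratio of 0.22, with Pim1, a kinase, 1.72-fold higher and no other member 1.5-fold apart. The unfolded protein response list had a median of -0.15 and the matrix protease list one of -0.12, while the cell cycle list was at -0.063. With each class weighted alike the latter pair were at -0.22 and -0.23, and their highest values over 14 alternatives were -0.064 and -0.042. Besides the list of Wnt agonists and trophic factors, lists whose sign depended on the processing were those of retinoid and lipid genes, at -0.22, basement membrane, at -0.079, and dissociation stress, at 0.055. In all, 165 of 9041 measured genes were at least 2-fold higher and 86 as much lower, counted by size only. These counts were 66 and 25 with a minimum of 50 CPM, 314 and 196 with none and 103 and 44 with 10 CPM added, and 50 genes were 2-fold lower with each class weighted alike. Adding 10 CPM by construction draws ratios of low genes towards 0. With it, the log2 ratios of the 12 highest genes by the naming rule ran from 1.57 to 3.975. Those of the 12 lowest ran from -3.23 to -1.11.

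**Figure D2:**
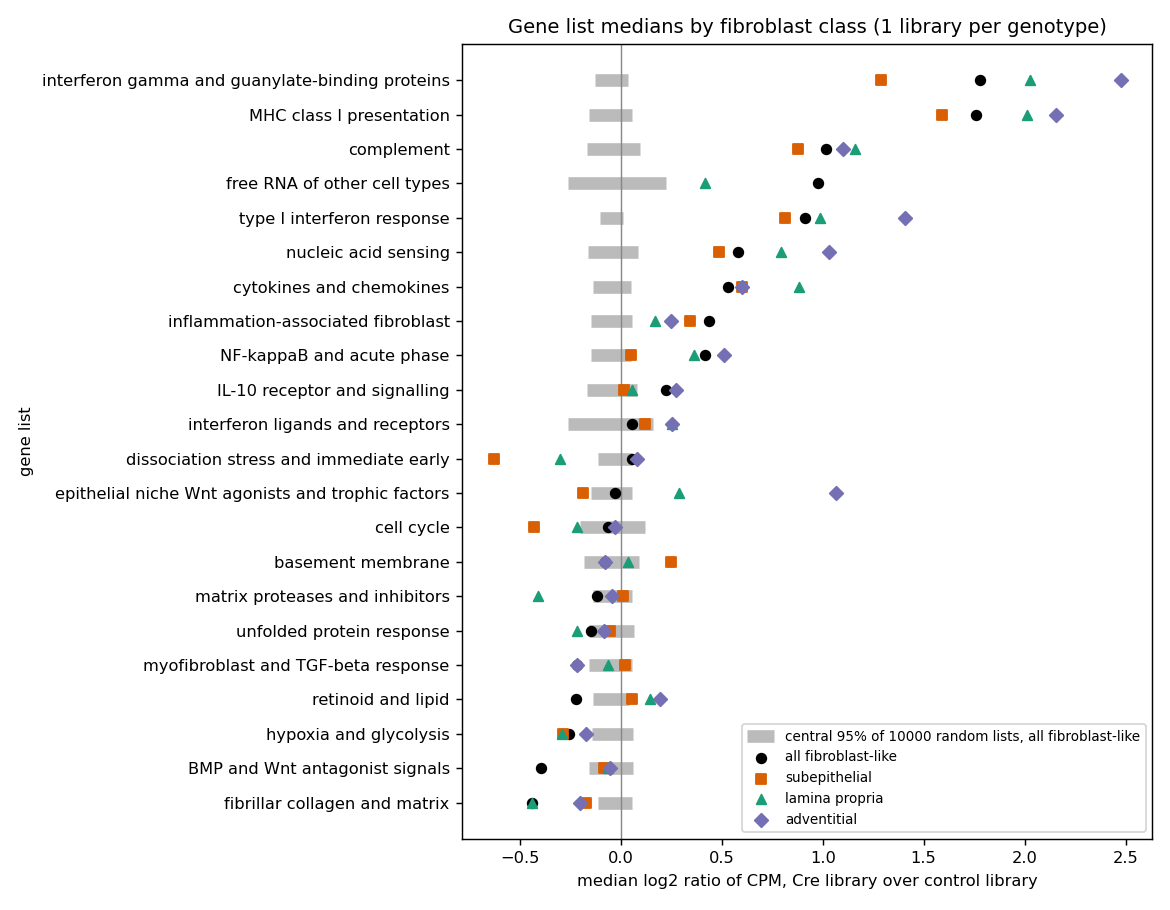
Median log2 ratio of CPM, Cre over control, of each fixed gene list, for all fibroblast-like cells (black) and for 3 fibroblast classes (colours), with grey bars for the central 95% of 10000 random lists in all fibroblast-like cells. The interferon gamma, MHC class I and type I interferon lists lie right of the grey bars, with medians of 1.78, 1.76 and 0.91 in all fibroblast-like cells.

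The type I list was higher in each fibroblast class compared. Its median log2 ratio was 1.41 in adventitial fibroblasts, where 48 of 54 measured members were at least 1.5-fold higher, 0.99 in lamina propria fibroblasts, with 44 of 52, and 0.81 in subepithelial fibroblasts, with 29 of 50 and 1 lower. The dissociation stress list, a possible sign of handling, shares Socs3 and Zfp36 with the IL-10 receptor and signalling list. The stress list had a median of -0.63 in subepithelial fibroblasts, with 15 of 29 members lower and 1 higher. It was at -0.30 in lamina propria fibroblasts, with 3 of 30 lower and 1 higher, and at 0.079 in adventitial fibroblasts. In cluster 11, led by Epyc, Ptx3 and Sfrp4, the type I median was 0.53. Isg15 was 4.42-fold higher in adventitial, 2.47-fold in lamina propria and 2.29-fold in subepithelial fibroblasts. In adventitial cells Saa3 had 0 UMIs in the control library, which allows up to 0.229 CPM, and was at 134 CPM in the Cre library. The lowest genes were Cd36, Cck and Stmn2 in lamina propria, Gap43, Stmn4 and Tubb4a in adventitial and Ociad2, H2ac8 and Mt3 in subepithelial fibroblasts. The classes span clusters of different libraries, as given above, and the lamina propria median was 0.35 when clusters were named by folds against all cells.

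Counted per cell, interferon list UMIs were also higher in the Cre library. After thinning, the median fibroblast-like cell held 11 list UMIs in the control and 18 in the Cre library. The 10th percentiles were 5 and 7 and the 90th 21 and 40. The count sums all list members, so abundant ones weigh most. In fibroblast-like cells Ifitm3 was at 1583 and 2766 CPM and Ifi27l2a at 1268 and 2656 CPM. A cell with 5 list UMIs is therefore not called a cell with an interferon response. At least 5 list UMIs were found in 91.9% (91.3 to 92.5) of 8732 control and 97.0% (96.6 to 97.4) of 7332 Cre cells, with 745 and 436 shallower cells left out. Without thinning the shares were 95.7% and 98.4%, at median depths of 6652 and 7554 UMIs, and after thinning to 1000 UMIs they were 59.4% and 81.4%. The list is not restricted to 1 cell type, so no kept type gives its background; in smooth muscle-like cells, at median depths of 6413 and 6384 UMIs, the thinned shares were 60.0% and 87.7%.

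**Figure D3:**
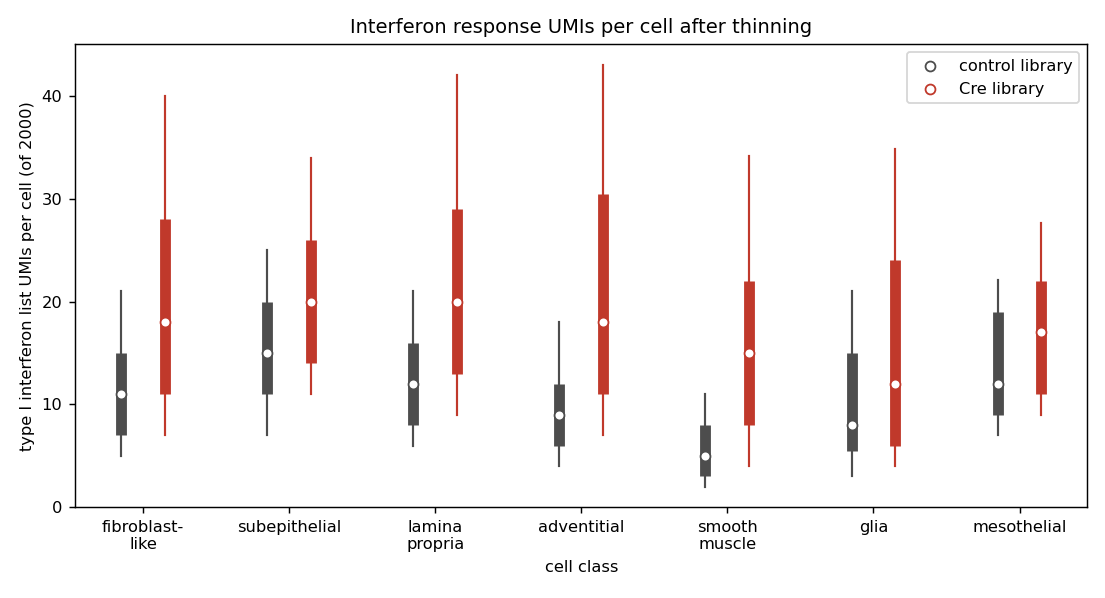
Type I interferon list UMIs per cell after thinning to 2000 UMIs, by cell class, in the control library (grey) and the Cre library (red), 1 library each; circles are medians over cells, thick bars run from the 25th to the 75th and thin lines from the 10th to the 90th percentile of cells. The median of fibroblast-like cells is 11 in the control and 18 in the Cre library, and that of smooth muscle-like cells 5 and 15. The count sums all list members, so in fibroblast-like cells the abundant Ifitm3 and Ifi27l2a weigh most.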

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

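No test was run in this part: with 1 library per genotype the differences between cell classes were not tested. The dissociation stress and immediate early list had a median log2 ratio of 0.079 in adventitial fibroblasts, -0.30 in lamina propria fibroblasts and -0.63 in subepithelial fibroblasts. It was picked out because, among the 3 named fibroblast classes, it lay above the 95th percentile of random lists in at least 1 and below the 5th in another, with medians of opposite sign. For the same reason the list of Wnt agonists and trophic factors was picked out, with medians of 1.07 in adventitial, 0.29 in lamina propria and -0.19 in subepithelial fibroblasts. Cluster 11 was not searched; with it, the same would hold for the lists of retinoid and lipid genes, at -0.23 there and 0.19 in adventitial fibroblasts, and of myofibroblast genes, at 0.21 and -0.22. It would also hold for matrix proteases, at 0.11 there and -0.41 in lamina propria fibroblasts, and for hypoxia and glycolysis, at 0.13 and -0.29.

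The type I interferon list also had a positive median log2 ratio in barcodes left out of the report's comparisons, some of which entered alternatives with looser filters or with doublets kept. In the 330 control and 214 Cre barcodes that failed the cell filter its median log2 ratio was 0.37, with 4287 and 4607 CPM over the whole list, and in the 479 and 97 barcodes called doublets it was 0.92, with 5815 and 10543.5 CPM.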

How the results depend on the processing

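The alternatives that rank genes differently for naming clusters were chosen after seeing the data; the others were fixed before. No paired analysis was possible because the groups share only replicate number 1, with 1 library each. The split by sex was not run, since 1 control and 0 Cre cells had Y-linked UMIs without Xist. The type I list median was positive under all 14 alternatives, from 0.70 to 1.03. Of 336 log2 ratios of the 24 highest and lowest genes by the naming rule under 14 settings, 0 turned sign. These genes were picked for their extreme ratios in the same counts, and CPM minimums and added CPM cannot turn a sign. The count is therefore no support for the genes. Causes were not tested, except that pseudocounts, CPM minimums, UMI minimums and thinning act by construction. Il10ra, at 1 and 5 UMIs in fibroblast-like cells, was too sparse to compare. Its upper limits were 0.0855 CPM in the control and 0.188 CPM in the Cre library.

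The lamina propria share had a log2 ratio of -0.61, which became 1.02 with at least 1000 genes and at most 5% mitochondrial UMIs (the strict filter), 1.01 with at least 200 genes and at most 20% (the loose filter), 0.25 with doublets kept, 0.049 with no gene kept out of the variable genes, 0.60 at resolution 2 and 0.65 with naming by folds against all cells. It was -0.36 at resolution 0.5, -0.14 with each library clustered on its own and -2.75 with naming by folds within the home library without a minimum. The adventitial share, at 0.41, was 0.495 (strict filter), 0.20 (libraries apart) and 0.74 (resolution 2), and the subepithelial share, at -1.05, was -1.60 (strict filter) and -1.69 (loose filter).

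With each class weighted alike 50 genes were 2-fold lower, the type I median was 1.03, and the medians of basement membrane (0.12), stress (-0.23) and retinoid (0.022) genes turned sign; thinning put stress at -0.0019. With a mean of at least 50 CPM, 66 genes were higher and 25 lower; type I medians were 0.87 in fibroblast-like, 1.21 in adventitial, 0.87 in lamina propria and 0.56 in subepithelial cells. With no minimum, 314 were higher and 196 lower, and medians were 1.05 in lamina propria and 0.89 in subepithelial cells. With 10 CPM added, 103 were higher and 44 lower, and medians were 0.70, 1.01, 0.77 and 0.66 in the same order. Type I medians were 0.88 in fibroblast-like and 0.94 in lamina propria cells for the mean of each cell's CPM, and 1.29 (thinned) and 1.21 (resolution 2) in adventitial cells. In lamina propria cells they were 0.87 with TMM, 0.87 with the median of ratios, which shift all ratios there by -0.12, 0.93 (strict filter), 0.88 (loose filter), 0.92 (doublets kept), 0.90 (resolution 2), 0.35 (all cells) and 0.71 (home library). In subepithelial cells the median was 0.87 with the loose filter.

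Control and Cre cells with enough list UMIs were 60.1% and 82.5% at 10 UMIs, 99.0% and 99.7% at 2, 59.4% and 81.4% thinned to 1000, 99.2% and 99.85% thinned to 4000 and 95.7% and 98.4% unthinned; the control share was 91.2% with the loose filter and 91.0% with no gene kept out.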

Other observations

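The tests of free RNA, class make-up, shared reads and batch were chosen after the results they concern were seen; those of a strain variant and of colon segments were written down before.

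The type I interferon list also had a positive median in the other cell classes compared, but in some of them most members were not 1.5-fold higher. In smooth muscle-like cells, 717 in the control and 183 in the Cre library, 42 of 47 measured members of the type I list were at least 1.5-fold higher, with a median log2 ratio of 1.52. H2-K1 was 9.54-fold higher there (8.87 to 10.3), and Cxcl9 had 0 and 134 UMIs, where 0 allows up to 0.789 CPM. The dissociation stress list, a possible sign of handling, had 14 of 30 members at least 1.5-fold lower in these cells and a median of -0.56. The type I median was 0.82 in glia-like cells, 79 and 122, with 30 of 48 higher and 2 lower. In mesothelial-like cells, 61 and 45, it was 0.46, with 21 of 56 higher and 3 lower, Isg15 at 173 and 218 CPM and Irf7 at 59.1 and 42.5 CPM. In cells resembling interstitial cells of Cajal, 38 and 60, the type I median was 0.17, at percentile 87.7 of random lists, with 15 of 50 members higher and 11 lower and Isg15 at 220 and 91.8 CPM. Transcripts of other cell types differed in that class: the free RNA list had a median of 2.43 over 6 measured members, and Acod1 and Wfdc17, both known from myeloid cells, had 0 UMIs in the control and 77 and 56 in the Cre library. In lymphatic endothelial-like cells, 42 and 44, the type I median was 0.88 with 32 of 54 higher and 8 lower, while the fibroblast gene Col3a1 had 114 and 1 UMIs. Over all 9048 genes measured there, 1701 were at least 2-fold higher and 1614 as much lower. In cells resembling interstitial cells of Cajal these counts were 1016 and 876 of 9868, so ratios in such small classes spread widely.

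MHC class II genes were higher in some classes of the Cre library. In glia-like cells 5 of 5 measured members were at least 1.5-fold higher, in mesothelial-like cells 4 of 5, in lamina propria fibroblasts 4 of 4 and in lymphatic endothelial-like cells 6 of 6. In cells resembling interstitial cells of Cajal 1 of 3 was higher and the median log2 ratio was -0.35. H2-Eb1 had 1 UMI in glia-like cells of the control and 109 in those of the Cre library, and 0 and 62 in mesothelial-like cells, where 0 allows up to 5.89 CPM. Over all kept cells Cd74, which antigen-presenting cells express, was at 5.48 and 31.5 CPM. The sort excluded CD45-positive cells, and these differences were not tested.

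The first pattern weighed is the higher interferon lists in the Cre library. If free RNA of other cells made up a like part of the UMIs in all classes, it would add alike to each. The excess of thinned list UMIs per cell was 12.3 in adventitial and 6.00 in subepithelial fibroblasts, a ratio of 2.05 (1.89 to 2.23). Under that premise this argues against free RNA as the whole source. The premise is not exact, since median depths in control and Cre were 5228 and 7359 UMIs in adventitial and 6532 and 6695 in subepithelial fibroblasts. The mix of fibroblast classes is argued against by a median log2 ratio of 1.03 with each of the 3 named classes weighted alike, against 0.91. Within classes the libraries filled different clusters, and Ifit1 was among the leading genes of cluster 3, with 72 control and 1499 Cre cells, so the mix of cells inside a class stays open. Batch and genotype cannot be told apart with 1 library per genotype, and genotype, inflammation of individual mice and handling stay open.

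The second pattern is that H2-Q6 and H2-Q7 stood further apart than other class I genes. A strain variant at these genes is a candidate explanation, and the test written for it asked for at least 10-fold in cells of equal type I list UMIs. In 5122 matched cells per library they had together a ratio of 27.1 (up to 29.8), while the other 15 class I members had a median ratio of 2.03 and the type I list one of 1.32. Reads shared between paralogs cannot be told apart from a difference in these genes: the lowest of 10 measured H2 genes, H2-M3, had a log2 ratio of 0.53, but where H2 genes are higher anyway a gene can lose reads and still be higher. The ratio of 27.1 met the 10-fold bound, but in matched cells the type I list and the other class I members also stayed higher. Matching on type I UMIs thus did not equalise the response, and it does not equalise other stimuli. The test therefore cannot tell a strain variant from a stronger response of these genes. Genotype and shared reads stay open beside strain.

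The third pattern is the set of 12 lowest genes by the naming rule, among them Cd36, Stmn2 and Nrg1. The mix of the 3 named classes is argued against as the whole source by a median log2 ratio of -1.76 with each class weighted alike, against -2.50. Weighting does not equalise clusters inside a class, and Cd36, Tbxas1, Agt and Grip1 were among the leading genes of cluster 7 (1187 control and 21 Cre cells), Stmn2 of cluster 0 (3112 and 148) and Nrg1 of cluster 13 (216 and 18), so the mix of cells inside a class stays open. A different share of colon segments was tested on posterior Hox genes, whose median log2 ratio was -0.14 (-0.23 to -0.050) over 5 measured genes. That met the bound written beforehand against segments, but the bound was set aside because the members went both ways, Hoxa13 at -0.64 and Hoxd13 at -0.49 against Hoxd11 at 0.32, so segment and genotype cannot be told apart for these genes.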
